A study of Mus musculus with 7 samples.

How the data were processed

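The study measured messenger RNA in 7 grafts of B16F10 melanoma cells in female C57BL/6J mice, 3 from control animals (NC) and 4 from animals given Zelnorm by mouth. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the TruSeq Stranded mRNA kit, which keeps the strand of each transcript. The authors deposited 1 table of raw read counts per gene, with 21878 genes and 1 column per library. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq, without versions or order, and the genome builds named are GRCh38, a human build, and GRCm38, a mouse build. The strand setting of the counting, the annotation release and any filter are not given in the sources used here. The gene identifiers in the table are mouse ones, and coordinates come from the reference gene table of GRCm38.p6, in which 21727 genes were found by their identifier. For 27 genes whose symbols had been turned into dates, the symbol was restored from the identifier. Mitochondrially encoded genes, Xist and the constant regions of immunoglobulins and T cell receptors were not analysed here. Reads that fit several near-identical genes (Ifi200 and Schlafen clusters, MHC class I genes, Ly6 genes, ribosomal protein genes with their pseudogenes) leave those counts uncertain.

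The columns name the group of each library but carry none of the replicate numbers of the sample titles, so each column was assigned to its group only. The labels give no batch. Library totals ran from 16903598 to 19666598 counts, and the 10 most abundant genes held between 6.70% and 7.28% of them. A floor of 3 counts was used for detection. The floor covers counting error only, whereas the SD and SE given below include the spread between libraries. Counts of every pair of libraries were compared over genes with a mean of at least 10 counts, and the chi-square per degree of freedom lay between 6.53 and 20.9, so no library was a copy of another.

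Genes with enough counts were kept by the filterByExpr rule (12997 genes), libraries were scaled by TMM (factors from 0.986 to 1.01) and groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.111. The SE of a log2 fold change was derived from its F statistic. CPM values are counts scaled by the TMM-adjusted library size, and means are given with the SD. Lists of genes for cell types and pathways, 50 in number with 836 genes, were fixed before the data were examined, as were the comparison, its tests and the alternatives unless stated otherwise. Of these genes, 806 were in the table, and 47 lists had at least 3 testable members. Plasma cells (2 testable members), sex-linked genes (0) and mitochondrially encoded genes (0) were not tested as lists. The 47 lists were tested with camera from limma 3.58.1, with an inter-gene correlation preset at 0.01 and with an estimated one, and with fry, whose directional test asks whether a list moves one way and whose mixed test asks for change in either direction. For each list the edgeR p of its members was also adjusted over the list alone. The level of a list in a library is the mean of log2 CPM of its members with a prior count of 2, and groups were compared by an exact permutation test over all 35 splits of 7 libraries into 3 and 4, 2-sided, whose smallest possible p is 0.0286. Adjusted p-values of lists come from these limma functions unless an exact permutation test is named.

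Genes were named by a rule set in advance. As fewer than 6 genes passed the adjusted threshold, the 10 genes per direction with the smallest p were taken, among those with a mean log2 CPM of at least 1, libraries of the groups not overlapping, and a gene symbol that is not a gene model. Up to 4 members of each list with the smallest p were added, as were serotonin receptors, pigment cell genes and a set of immune markers, whatever their test. Members of lists added later, and Ctsb and Spry4, were chosen after their values were seen. The alternatives were other scalings (RLE, upper quartile), other filters, DESeq2 1.42.0, limma voom with and without sample weights, a robust edgeR fit, the leukocyte level as a covariate, removal of the 10 most abundant genes, other thresholds and leaving out each library. A covariate for the skeletal muscle level, leaving out the 3 libraries with the most muscle transcripts, the leukocyte covariate with 1 library left out for the type I interferon list, and DESeq2 on the 12997 genes tested by edgeR (its planned run used 16921 genes and its own filtering) were added after seeing the data. A planned fit with the replicate number as a block was not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

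The tests were tried on simulated counts made from the means and sizes of the real libraries, for the comparison of Zelnorm with NC. Of 200 genes raised or lowered by 1 on the log2 scale among 12997 simulated genes, edgeR recovered 84.5% with 13 false calls and DESeq2 88% with 21. At a change of 2, edgeR recovered 94.5% with 14 false calls and DESeq2 92.5% with 23. A type I interferon list shifted by 0.5 was called by camera, and 0 of 45 unchanged lists were called by camera or fry. The simulated genes varied independently, so this does not show how often lists whose genes vary together are called falsely. On the real counts, splits of the libraries other than the real one gave between 9 and 31 camera calls at the preset correlation. The split with 31 (NC_5, NC_6 and MBZ_13 against the rest) kept most of the treatment grouping.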

Results

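Tumour RNA was sequenced from 7 grafts of B16F10, a pigmented mouse melanoma cell line, grown in female C57BL/6J mice. The control group (NC) held 3 tumours. The other group held 4 tumours from mice given Zelnorm by mouth at 1.25 mg/kg every 2 days. Zelnorm is the trade name of tegaserod, a partial agonist of the 5-HT4 serotonin receptor used for constipation-predominant irritable bowel syndrome. The libraries are named here by their column names in the count table, NC_5, NC_6 and NC_10 for the controls and MBZ_9, MBZ_11, MBZ_13 and MBZ_15 for the treated tumours. The labels use the letters MBZ for the group they call Zelnorm without saying what the letters stand for, and nothing in the counts checks which drug was given. The libraries held between 16903598 and 19666598 counts assigned to genes, with group ranges of 18079258 to 19547390 (NC) and 16903598 to 19666598 (Zelnorm). A count of 3, taken as the floor of detection, corresponded to between 0.153 and 0.177 CPM (counts scaled to library size), and such floors cover counting error only. The labels describe mice assigned to groups at random but do not state that each library came from its own mouse, so the p-values measure at most the spread between these samples. Camera p-values at the preset correlation of 0.01 do not measure that spread, as they treat the members of a list as nearly independent. The estimated correlation ran from -0.064 (Schwann and neural crest list) to 0.89 (skeletal muscle list) and was 0.69 for the type I interferon list.

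The libraries resembled each other closely. Pearson correlations of log2 CPM were 0.983 to 0.989 among NC libraries, 0.984 to 0.989 among Zelnorm libraries and 0.980 to 0.989 between groups. No pair agreed within sampling noise, since the chi-square per degree of freedom was at least 6.53 in every pair. The first principal component carried 29.0% of the variance, and all 4 Zelnorm libraries lay above all 3 NC libraries on it (exact permutation test, 2-sided p = 0.0286, the smallest that 3 against 4 libraries allow).

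The series title asks whether the drug acts on the tumour's immune microenvironment, and the comparison of the 2 groups addresses that question. Genes of the interferon response, antigen presentation, complement, monocytes and macrophages were higher in the Zelnorm tumours, with list medians between 0.69 and 1.10 on the log2 scale. The medians of the pigment cell and proliferation lists lay near 0. Genes of cholesterol synthesis, ribosomal proteins and oxidative phosphorylation were lower by small amounts. Of these and all other lists, none passed the test with an estimated correlation between genes (smallest adjusted p = 0.118). Single genes rarely passed the test across all genes. Of 12997 genes tested, 4 rose and 0 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), while 902 were higher and 439 lower at an unadjusted p under 0.05, where chance alone gives about 650 in all and other splits of the libraries gave up to 1439, so chance cannot be excluded for that count.

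The 4 genes that rose were Cybb, Ifi204, Ly6a and Helz2, and each was higher in every Zelnorm library than in every NC library. Cybb (GRCm38 chromosome X, 9435252 to 9487766), which encodes the catalytic subunit of the phagocyte NADPH oxidase, went from 9.74 ± 0.493 CPM (SD, n = 3) to 19.7 ± 0.917 (SD, n = 4), a log2 fold change of 1.02 ± 0.09 (SE; edgeR adjusted p = 0.00533). Ifi204 (chromosome 1, 173747293 to 173767069), an interferon-inducible sensor of nucleic acid, went from 7.13 ± 0.718 to 16.3 ± 1.34 CPM (log2 fold change 1.19 ± 0.12, edgeR adjusted p = 0.00533). Ly6a (chromosome 15, 74994877 to 74998031), which encodes the surface antigen Sca-1, went from 20.2 ± 2.61 to 40.6 ± 3.47 CPM (1.01 ± 0.10, edgeR adjusted p = 0.00533). Helz2 (chromosome 2, 181227615 to 181242058), a helicase and transcriptional coactivator, went from 31.2 ± 0.379 to 48.3 ± 4.84 CPM (0.63 ± 0.08, edgeR adjusted p = 0.0467). Ifi204 belongs to a cluster of related genes, so part of its count is uncertain where reads fit several of them. DESeq2 called 206 genes at the same threshold, 171 higher and 35 lower, among them all 4 genes called by edgeR, and 216 when run on the same 12997 genes as edgeR, an alternative chosen after seeing the data. Without NC_5 edgeR called 0 genes (977 at an unadjusted p under 0.05, and 110 by DESeq2), while without NC_10 it called 161 and without MBZ_15 it called 21.

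**Figure D1:**
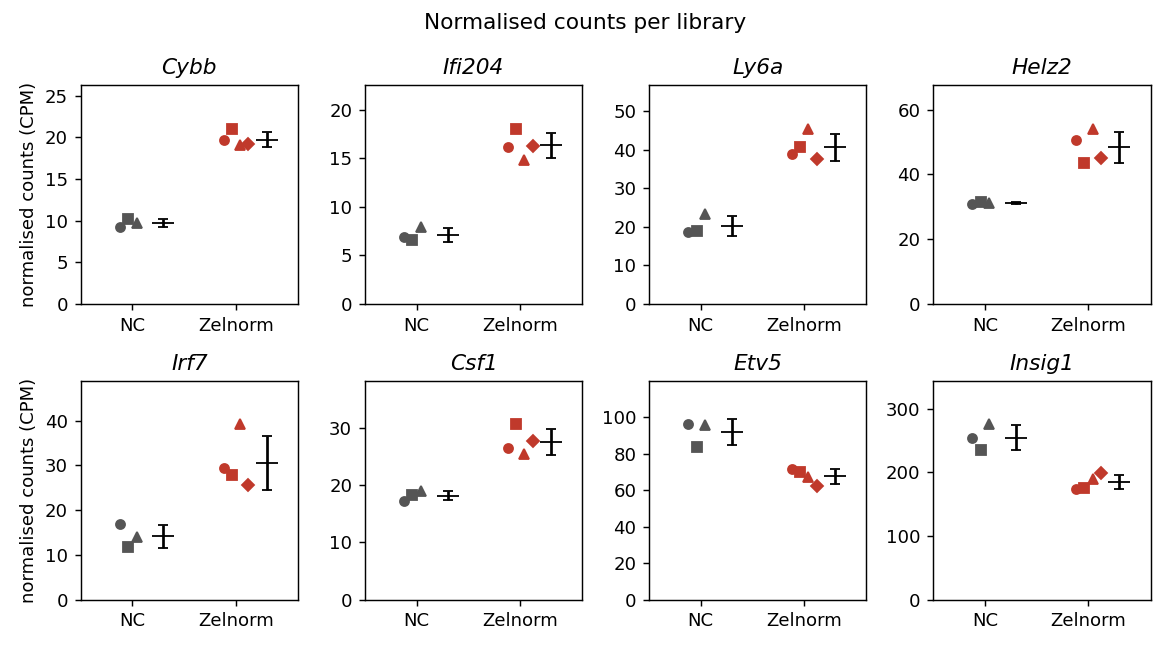
Normalised counts (CPM, linear axes from 0) of 8 genes in each library, NC in grey and Zelnorm in red, with the group mean and SD as a black bar beside the points. Cybb, Ifi204, Ly6a and Helz2 passed the adjusted threshold, whereas Irf7, Csf1, Etv5 and Insig1 separate the groups without passing it.

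Among the genes next in order of p that separated the groups, none passed the adjusted threshold. On the higher side stood Oasl2 (log2 fold change 1.18 ± 0.17) and Irf7 (1.10 ± 0.16), both of the interferon response, and Csf1, the macrophage colony-stimulating factor (0.60 ± 0.09). Slfn2 (1.05 ± 0.16) and Mnda (1.23 ± 0.18) had the same edgeR adjusted p as these, 0.0559, and Cfb, complement factor B, followed (0.83 ± 0.13, adjusted p = 0.0646). On the lower side stood Ier3 (-0.58 ± 0.08), Insig1, a sterol-regulated gene of the endoplasmic reticulum (-0.47 ± 0.07), the transcription factor genes Etv5 (-0.44 ± 0.07) and Etv4 (-0.79 ± 0.15), and Adam12 (-0.42 ± 0.08). They were followed by Rpl39 (-0.44 ± 0.08), Rlbp1 (-0.52 ± 0.11), Rcor2 (-0.33 ± 0.07), Rps29 (-0.50 ± 0.11) and Gjc3 (-0.36 ± 0.08). The edgeR adjusted p of these 10 genes ran from 0.0559 to 0.152. The ribosomal genes have many processed pseudogenes, which makes their counts uncertain. Across all tested genes, 693 had every Zelnorm library above every NC library and 555 had every one below, together 9.60%. Chance gives 5.71% on average, but the share in the other splits of the libraries was not counted, so chance cannot be excluded for it.

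Gene lists fixed before the data were examined were compared next. Of 47 lists tested with camera at a preset inter-gene correlation of 0.01, 25 rose and 5 fell at an adjusted p under 0.05, a number of calls that 3 of the 35 splits of the libraries into 3 and 4 reached, the real one included. With the correlation estimated from the data none passed (smallest adjusted p = 0.118, 13 lists at an unadjusted p under 0.05). Over all 12997 genes, no member of any of the 47 lists passed the edgeR threshold, so the member counts given per list are those adjusted over the list alone. The fry test for movement in one direction called 2 lists, and its mixed version called 13. The exact permutation test of the mean level of a list per library called 0 lists after adjustment (smallest adjusted p = 0.149), with 9 lists at 0.0286, the smallest p that this design allows.

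**Figure D2:**
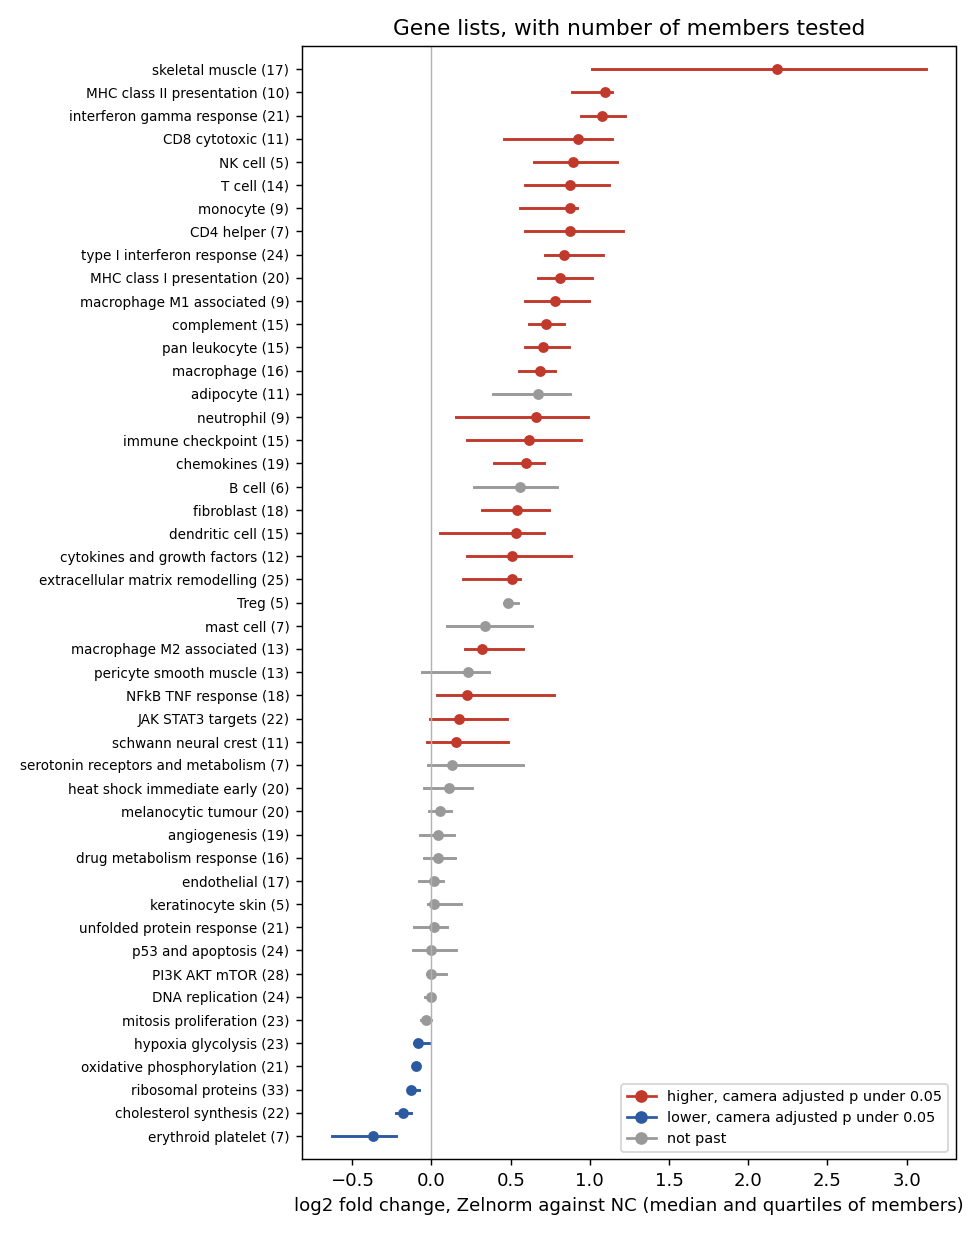
Median log2 fold change of each of the 47 gene lists (points) with the quartiles of its members (lines), Zelnorm against NC, and the number of members tested in brackets. Interferon, antigen presentation and myeloid lists lie to the right, ribosomal and cholesterol synthesis lists slightly to the left, and skeletal muscle far to the right with a wide spread.

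The type I interferon response had the smallest p of all lists in camera at the preset correlation, whereas with an estimated correlation complement did. All 24 measured members were higher in the Zelnorm tumours, 20 of them in every Zelnorm library above every NC library, with a median log2 fold change of 0.83. Adjusted over the list alone, 22 rose and 0 fell, against 0 over all genes tested by edgeR. Examples that rose adjusted over the list alone were Irf7, from 14.2 ± 2.61 to 30.5 ± 5.98 CPM, Rtp4, from 12.9 ± 2.94 to 29.8 ± 7.69 CPM, and the signalling factor Stat2, from 21.1 ± 2.29 to 34.8 ± 4.70 CPM (n = 3 and 4, SD). The list rose in camera (adjusted p = 4.23e-46), with an adjusted p = 0.13 with an estimated correlation, and its median stayed between 0.66 and 0.995 when each library was left out in turn. The interferon gamma response list, made of guanylate-binding proteins, immunity-related GTPases and inducible chemokines, had 21 of 21 members higher and a median of 1.07 (camera adjusted p = 1.65e-19, and adjusted p = 0.187 with an estimated correlation). Of these, 12 rose adjusted over the list alone, among them Gbp7 (log2 fold change 1.29 ± 0.35) and Socs1 (1.04 ± 0.29). NC_10 had a low level on this list, 2.85 against 4.82 and 5.09 in the other NC libraries (mean log2 CPM), and without it the median was 0.68. Transcripts of interferon gamma itself were few, with 0 to 5 counts of Ifng in NC and 3 to 16 in Zelnorm libraries.

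Most antigen presentation genes were higher as well. All 20 genes of MHC class I presentation were higher (median 0.81, camera adjusted p = 8.52e-26, adjusted p = 0.165 with an estimated correlation), and 15 rose adjusted over the list alone. The class I heavy chain gene H2-K1 went from 290 ± 80.2 CPM in NC to 565 ± 116 in Zelnorm tumours. H2-Q7 (log2 fold change 1.12 ± 0.18) and H2-T23 (1.02 ± 0.22) rose adjusted over the list alone as well, though reads of these near-identical genes cannot be fully told apart. For MHC class II, 9 of 10 genes were higher (median 1.10, camera adjusted p = 1.30e-12, adjusted p = 0.165 with an estimated correlation) and 8 rose adjusted over the list alone. These included the invariant chain Cd74, from 151 ± 28.0 to 363 ± 149 CPM, H2-Eb1 (1.19 ± 0.28) and H2-Ab1 (1.12 ± 0.27). Of 15 complement genes all were higher (median 0.72, camera adjusted p = 4.14e-21, adjusted p = 0.118 with an estimated correlation) and 11 rose adjusted over the list alone, such as C4b (0.93 ± 0.15) and C1s1 (0.85 ± 0.15).

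**Figure D3:**
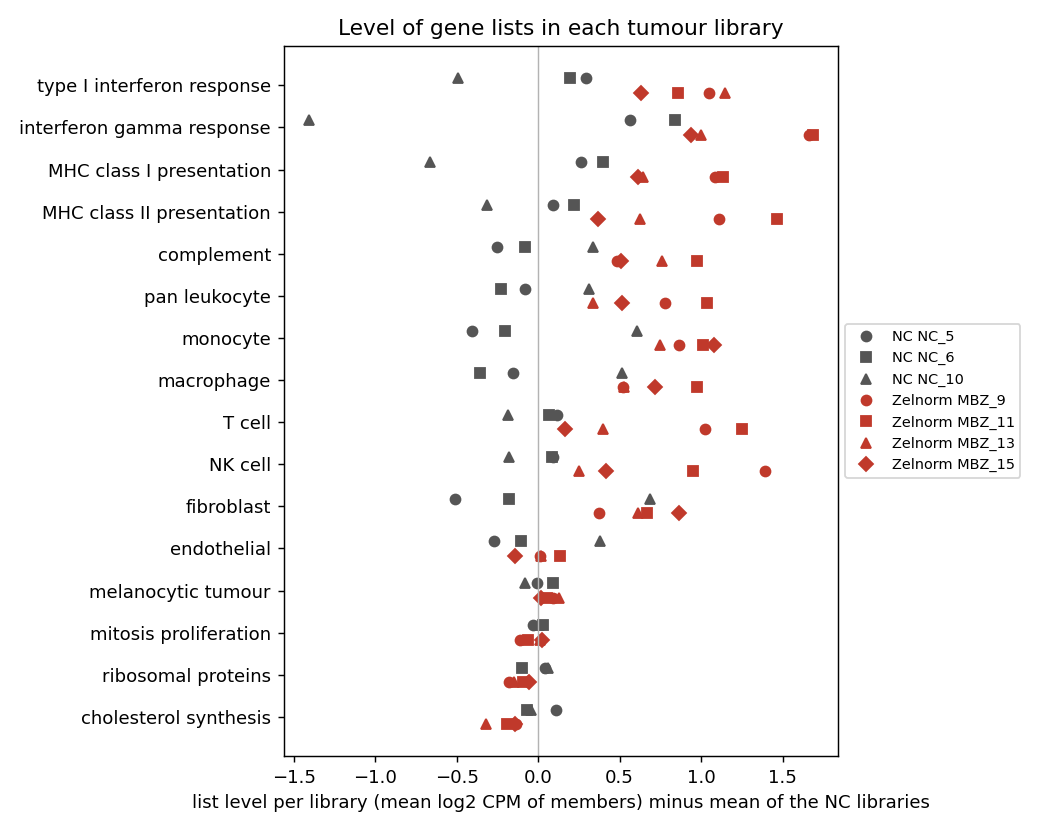
Level of 16 gene lists in each library, as the mean log2 CPM of the members minus the mean of the NC libraries, with NC in grey and Zelnorm in red and a symbol per library. All Zelnorm libraries lie above all NC libraries for the lists from type I interferon down to NK cell, while the fibroblast, endothelial, melanocytic, mitosis and ribosomal lists overlap.

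Leukocyte transcripts were more abundant in the Zelnorm tumours. All 15 genes of the pan-leukocyte list were higher (median 0.71, camera adjusted p = 1.72e-13, adjusted p = 0.177 with an estimated correlation), and 10 rose adjusted over the list alone, including Ptprc, which encodes CD45, from 11.7 ± 3.21 to 19.6 ± 3.50 CPM, and Coro1a (0.71 ± 0.19). Macrophage genes were higher in 16 of 16 cases (median 0.69, camera adjusted p = 4.31e-15, adjusted p = 0.177 with an estimated correlation), with 11 risen adjusted over the list alone, such as Ctss (0.96 ± 0.17), Fcgr1 (0.90 ± 0.20) and C1qc (0.72 ± 0.19). Adgre1, the macrophage marker F4/80, had 19.5 ± 9.68 CPM in NC and 32.1 ± 7.25 in Zelnorm tumours (log2 fold change 0.71, 0.47 without NC_6 and 1.20 without NC_10, edgeR adjusted p = 0.404). Monocyte genes had a median of 0.87 (camera adjusted p = 7.41e-12, adjusted p = 0.132 with an estimated correlation), with Ly6c2 at 1.46 ± 0.25 and 6 of 9 risen adjusted over the list alone. The macrophage median was 1.04 without NC_10, and the monocyte median was 0.53 without NC_5. Genes associated with inflammatory (M1) macrophages had a median of 0.78 (camera adjusted p = 1.63e-05, adjusted p = 0.118 with an estimated correlation), with 9 of 9 higher and 0 risen adjusted over the list alone (4 at an unadjusted edgeR p under 0.05). Those associated with M2 macrophages had a median of 0.32 (camera adjusted p = 0.0071, adjusted p = 0.514 with an estimated correlation), which was 1.09 without NC_10, and the call was absent without NC_6 (0.02) or NC_5 (0.08). Without the 3 libraries with the most muscle transcripts (NC_5, MBZ_11 and MBZ_15), an alternative chosen after seeing the data, the medians were 0.39 for macrophages and 0.36 for monocytes, and the M2 median was -0.04 with its call absent.

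Lymphocyte transcripts were sparse. The T cell list had a median of 0.87 with 14 of 14 genes higher (camera adjusted p = 9.20e-07, adjusted p = 0.204 with an estimated correlation), and only Thy1 rose adjusted over the list alone (0.47 ± 0.11), a gene that fibroblasts express too. Cd3e had 1.24 ± 0.427 CPM in NC and 2.21 ± 1.20 in Zelnorm tumours. In the CD8 and cytotoxic list (median 0.93, camera adjusted p = 0.000253, adjusted p = 0.332 with an estimated correlation) Cd8a rose adjusted over the list alone, from 1.23 ± 0.544 to 3.85 ± 1.64 CPM, whereas Gzmb was at 1.80 ± 0.510 and 3.75 ± 2.27 CPM and Prf1 at 1.66 ± 0.623 and 2.60 ± 1.66 CPM. Their log2 fold changes of 1.06 and 0.65 were 0.675 and 0.13 without MBZ_9, and that of Prf1 was 0.37 without NC_10. MBZ_9 and MBZ_11 had levels of 1.47 and 1.32 on this list, against 0.39 in MBZ_13 and 0.36 in MBZ_15, close to NC_5 at 0.36. CD4 helper genes had a median of 0.87 (camera adjusted p = 1.56e-06, adjusted p = 0.132 with an estimated correlation), with Il7r (1.31 ± 0.34) among those risen adjusted over the list alone. Natural killer genes, of which 5 of 14 were testable, had a median of 0.90 (camera adjusted p = 0.00202, adjusted p = 0.255 with an estimated correlation). Il2rb (1.17 ± 0.30) and Klrc1 (2.24 ± 0.59) rose adjusted over the list alone. Klrc1 had only 1 to 4 counts in NC libraries, near the floor of 3, and 8 to 19 in Zelnorm libraries. The camera call of the natural killer list was absent without MBZ_9 (median 0.35) or MBZ_11 (0.79). Foxp3, the regulatory T cell factor, was at 0.337 ± 0.104 and 0.769 ± 0.368 CPM, and Pdcd1 (PD-1) at 0.692 ± 0.625 and 1.88 ± 0.925 CPM. The log2 fold change of Pdcd1, 1.45, was 0.88 without NC_10 and 2.29 without NC_5. The regulatory T cell (median 0.49), B cell (0.56) and mast cell (0.34) lists were not past the threshold in camera (adjusted p = 0.0583, 0.0798 and 0.143). They passed it in some sets of 6 libraries: regulatory T cells without MBZ_15 (0.72), B cells without NC_10 (0.75) or MBZ_15 (0.73), and mast cells without NC_5 (0.73) or MBZ_9 (0.42). With an estimated correlation none did (smallest adjusted p = 0.185, 0.275 and 0.272). The B cell median was 0.36 without MBZ_9 and 0.35 without MBZ_11, and the regulatory T cell median 0.74 without NC_10. Dendritic cell genes had a median of 0.53 (camera adjusted p = 0.00153, adjusted p = 0.332 with an estimated correlation), which was 0.33 without MBZ_11. Neutrophil genes had a median of 0.66 (camera adjusted p = 0.0207, adjusted p = 0.332 with an estimated correlation), and the call was absent without any one of NC_5 (0.39), NC_6 (0.32), MBZ_11 (0.44) or MBZ_15 (0.39), while the median was 1.19 without NC_10.

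The immune checkpoint list had a median of 0.62 (camera adjusted p = 9.73e-06, adjusted p = 0.175 with an estimated correlation), and Cd274, which encodes PD-L1, rose adjusted over the list alone from 12.8 ± 4.81 to 21.9 ± 4.46 CPM, together with Entpd1 (0.55 ± 0.13) and Lgals9 (0.41 ± 0.10). The log2 fold change of Cd274, 0.78, was 0.52 without NC_10. Chemokine genes had a median of 0.60 (camera adjusted p = 1.72e-07, adjusted p = 0.18 with an estimated correlation), with Ccl7 risen adjusted over the list alone (1.07 ± 0.24). The cytokine and growth factor list, with a median of 0.51, also passed the directional fry test (adjusted p = 0.0382; camera adjusted p = 9.67e-05, and adjusted p = 0.118 with an estimated correlation), and Csf1 and Tgfb3 (0.30 ± 0.09) rose adjusted over the list alone. Targets and components of the JAK and STAT3 pathway had a median of 0.18 (camera adjusted p = 0.00305, adjusted p = 0.214 with an estimated correlation). There Osmr rose adjusted over the list alone (0.54 ± 0.12), Stat3 had 249 ± 29.3 and 297 ± 19.2 CPM and Socs3 had 23.7 ± 2.45 and 28.8 ± 3.74 CPM. In the NF-kappaB and TNF list (median 0.22, camera adjusted p = 0.00995, adjusted p = 0.255 with an estimated correlation, median 0.34 without NC_10) Vcam1 rose (1.02 ± 0.22) and Ier3 fell adjusted over the list alone.

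Other cells of the tumour bed moved unevenly. All 18 fibroblast genes were higher (median 0.54, camera adjusted p = 6.44e-11, adjusted p = 0.214 with an estimated correlation), with 5 risen adjusted over the list alone, such as Dcn (0.88 ± 0.21) and Lum (0.74 ± 0.22), and all 25 genes of matrix remodelling were higher with 0 risen and 4 at an unadjusted edgeR p under 0.05 (median 0.51, camera adjusted p = 2.04e-07, adjusted p = 0.332 with an estimated correlation). NC_10 had the highest NC level on both lists. Without it the medians were 1.09 and 0.83, without NC_5 they were 0.33 and 0.21, and without MBZ_15 the matrix median was 0.27. Endothelial (median 0.02), pericyte and smooth muscle (0.23) and angiogenesis (0.04) lists were not past the threshold in camera (adjusted p = 0.992, 0.208 and 0.781). Nor were the skin keratinocyte (0.02) and adipocyte (0.67) lists (adjusted p = 0.952 and 0.586). For the endothelial list the mean was -0.02 and the camera direction down, and for the keratinocyte list the mean was 0.27 and the camera direction down, against medians just above 0. The endothelial list passed without NC_10 (0.26) or NC_5 (-0.12), the pericyte list without NC_10 (0.45) and the adipocyte list without MBZ_9 (1.04) or MBZ_13 (-0.19). With an estimated correlation no set of 6 libraries passed for these lists (smallest adjusted p = 0.358, 0.111 and 0.516). The pericyte median was 0.02 without NC_5, and the adipocyte median was 0.35 without NC_5 and 1.02 without NC_10. Schwann and neural crest genes had a median of 0.15 (camera adjusted p = 0.0141, adjusted p = 0.175 with an estimated correlation, directional fry adjusted p = 0.0382), and Pmp22 rose adjusted over the list alone (0.73 ± 0.12). Their camera call was absent without NC_6 (median 0.06) or MBZ_11 (0.08), and the median was 0.29 without NC_5, 0.25 without MBZ_15 and 0.08 without MBZ_9. The red cell and platelet list had a median of -0.37 with 6 of 7 genes lower (camera adjusted p = 0.000965, adjusted p = 0.255 with an estimated correlation). Only the haemoglobin gene Hba-a2 fell adjusted over the list alone, at 17.1 ± 1.71 CPM in NC and 8.18 ± 3.87 in Zelnorm tumours, while of the platelet genes Pf4 was at 9.64 ± 9.41 and 8.98 ± 5.28 CPM and Itga2b at 0.498 ± 0.0486 and 0.753 ± 0.0817 CPM. The median of the list was -0.19 without MBZ_13, -0.62 without MBZ_11 and -0.56 without MBZ_15. Skeletal muscle genes had a median of 2.18 with a wide spread (camera adjusted p = 4.63e-06, adjusted p = 0.406 with an estimated correlation, 0 risen adjusted over the list alone and 8 at an unadjusted edgeR p under 0.05). Their summed CPM was 497 in MBZ_15, 229 in MBZ_11 and 105 in NC_5 but between 62.3 and 80.1 in the other 4 libraries, and the median was 1.19 without MBZ_15 and 5.39 without NC_5. Without those 3 libraries edgeR called 0 genes (547 at an unadjusted p under 0.05, and 51 by DESeq2). Besides those of macrophages and monocytes, the list medians were then 0.16 for fibroblasts, 0.25 for chemokines and 0.46 for complement, and the camera calls of matrix remodelling (0.02), neutrophils (-0.01), Schwann cells (0.14), JAK and STAT3 (0.13) and NF-kappaB (0.09) were absent, as was that of skeletal muscle (-0.0053). Calls gained there were regulatory T cells (0.52) and melanocytic genes (0.07) as higher, and mitosis (-0.09), angiogenesis (-0.11) and unfolded protein (-0.08) as lower, which made 20 lists higher and 8 lower, with none past the threshold with an estimated correlation (smallest adjusted p = 0.464).

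**Figure D4:**
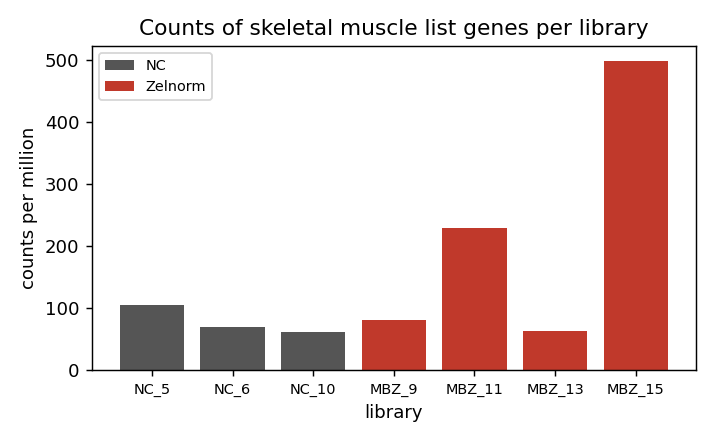
Summed CPM of the skeletal muscle list in each library (linear axis from 0), NC in grey and Zelnorm in red. MBZ_15 (497) and MBZ_11 (229) stand above the other libraries of both groups.

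The median of the tumour cells' own markers lay near 0. The melanocytic list had a median log2 fold change of 0.05 with 14 of 20 genes higher (camera adjusted p = 0.0942), and it passed without NC_6 (0.08) or MBZ_15 (0.06), though with an estimated correlation it did not (smallest adjusted p = 0.337). The median was 0.02 without NC_10 and 0.03 without MBZ_13. The smallest p in it belonged to Mitf, the master regulator of pigment cells, at 378 ± 37.7 CPM in NC and 573 ± 132 in Zelnorm tumours (log2 fold change 0.60 ± 0.16, edgeR adjusted p = 0.215), and to Bace2 (0.30 ± 0.09, edgeR adjusted p = 0.296). Pmel had 6289 ± 518 CPM in NC and 6608 ± 502 in Zelnorm tumours, Tyr 946 ± 76.2 and 894 ± 94.7, Dct 8337 ± 297 and 8296 ± 252, and Mlana 664 ± 16.8 and 643 ± 53.3, and none of these genes passed the test, over all genes or adjusted over the list alone. Mitosis genes had a median of -0.03 and DNA replication genes one of -0.0020 (camera adjusted p = 0.0647 and 0.42), and mitosis genes passed without NC_5 (-0.06), MBZ_13 (-0.05) or MBZ_15 (-0.07), and in no set of 6 libraries with an estimated correlation (smallest adjusted p = 0.275), while their median was -0.02 without MBZ_9. Mki67 was at 225 ± 22.3 and 220 ± 35.5 CPM. The PI3K, AKT and mTOR (-0.0013), p53 and apoptosis (-0.00083), unfolded protein (0.01), heat shock and immediate early (0.11) and drug metabolism (0.04) lists were not past the threshold (camera adjusted p = 0.781, 0.436, 0.448, 0.172 and 0.54). Mean and median differed in sign for the PI3K list (mean 0.07, camera direction up), the p53 list (mean 0.04, camera direction down) and the unfolded protein list (mean -0.03, camera direction down). The unfolded protein list passed without MBZ_15 (-0.02) and the heat shock list without NC_6 (0.12), neither of them with an estimated correlation (smallest adjusted p = 0.275 and 0.322). The heat shock median was 0.07 without NC_5, and the drug metabolism median was 0.02 without NC_10. The p53 and apoptosis list and the heat shock and immediate early list did pass the fry test for change in either direction (adjusted p = 0.00437 and 0.0211), and in the latter Jun rose (0.26 ± 0.07) and Egr1 fell (-0.61 ± 0.17) adjusted over the list alone.

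Cholesterol synthesis genes lay lower as a group. All 22 were lower in the Zelnorm tumours, 9 of them in every library, with a median log2 fold change of -0.18 (camera adjusted p = 1.30e-12, adjusted p = 0.169 with an estimated correlation). Only Insig1 fell adjusted over the list alone, from 255 ± 19.8 to 184 ± 11.3 CPM, while Sqle, squalene epoxidase, was at 258 ± 9.96 and 231 ± 9.16 CPM. Ribosomal protein genes were lower in 33 of 33 cases (median -0.13, camera adjusted p = 1.40e-10, adjusted p = 0.255 with an estimated correlation) and oxidative phosphorylation genes in 21 of 21 (median -0.10, camera adjusted p = 3.28e-05, adjusted p = 0.18 with an estimated correlation), with 0 fallen adjusted over either list alone and 11 and 2 at an unadjusted edgeR p under 0.05. Hypoxia and glycolysis genes had a median of -0.09 (camera adjusted p = 0.0181, adjusted p = 0.529 with an estimated correlation), a call that was absent without NC_5 (-0.02), MBZ_11 (-0.08) or MBZ_13 (-0.04). The scaling between libraries moved the median of all genes by less than 0.01, and the direction of these 4 lists was the same under each scaling tried.

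Serotonin receptor transcripts lay at or under the floor with few exceptions. Htr4, the receptor that Zelnorm activates, had 2, 1 and 0 counts in the NC libraries and 0 in all 4 Zelnorm libraries, so no difference was detectable at this depth. Htr2b was the only receptor with enough counts for the test, at 0.510 ± 0.172 CPM in NC and 0.713 ± 0.154 in Zelnorm tumours (log2 fold change 0.47, 0.30 without NC_6 and 0.78 without NC_10, edgeR adjusted p = 0.751). Htr7 had 1 to 4 counts in NC and 1 to 12 in Zelnorm libraries, and Htr2a had 0 to 3 in both groups. Htr1b, Htr3b and Htr5b had at most 2 counts in any library, and Htr1a, Htr1d, Htr1f, Htr2c, Htr3a, Htr5a and Htr6 had 0 in all 7. The list of serotonin receptors and metabolism had 7 testable genes and a median of 0.13 (camera adjusted p = 0.333).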

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

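The tests on the interferon genes and on muscle were chosen only after the result was seen, whereas those on ribosomal genes and on splits of the libraries were set beforehand. The gap of 1 library to the rest of its group was checked for 47 list levels and 37 named genes in the 4 Zelnorm libraries, where chance alone marks about 1 in 20 (4.2 in all), and 1 stood out. Mlana had 563.7 CPM in MBZ_9, far from the other Zelnorm libraries at 661.9 to 681.1 CPM.

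The interferon response was higher in the Zelnorm tumours (median log2 fold change 0.83 over 24 genes). More leukocytes as the cause were examined by a fit with the leukocyte level as a covariate. There the median was 1.305 and the lower quartile of the members 1.16, the lowest of both with 1 library left out being 0.8727 and 0.4574 (without NC_10). The groups do not overlap in that level (highest NC library 3.46, lowest Zelnorm library 3.49), so the fit extends a trend within groups beyond the levels they share. With an estimated correlation the list passed in none of these fits (camera adjusted p = 0.23 over all libraries and 0.0954 to 0.558 with 1 left out, against 0.13 without the covariate). The fit therefore cannot decide, and more leukocytes stay open as the whole cause or a part of it. NC_10, the control library lowest on this list, is not the whole cause, since the median without it was 0.6615. A smaller share of tumour cells would raise markers of all other cells alike. The endothelial median was 0.0186 (-0.12 without NC_5 to 0.26 without NC_10), against quartiles of 0.59 to 0.87 for leukocyte genes. Other medians were uneven, with 0.54 for fibroblasts, 0.23 for pericytes, 0.02 for keratinocytes and -0.37 for red cells and platelets. A smaller share of tumour cells alone would not give this uneven pattern, but a part in the rise stays open. A response of the tumours to the treatment remains open as a hypothesis, as do differences between tumours that the labels do not record.

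Skeletal muscle transcripts differed strongly between libraries. Of the 17 testable muscle genes, 88.2% had MBZ_11 and MBZ_15 as their 2 highest libraries, which is what muscle tissue in some tumour pieces would give, as would any joint change of these genes in those libraries. Myh4 had a log2 fold change of 4.77 ± 1.61 and Atp2a1 of 3.84 ± 1.32, with groups that overlapped, and these were 11.46 and 5.76 without NC_5 and 3.32 and 2.53 without MBZ_15. Myh4 had 39 counts in NC_5 and 0 in NC_6 and NC_10, so its value of 11.46 rests on no control counts and does not measure a size. Muscle attached to those pieces may account for the difference, which stays open, and no biological explanation was tested. With the muscle level as a covariate, edgeR still called 4 genes.

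Ribosomal protein genes were lower in the Zelnorm tumours (median -0.13). They have short transcripts, but genes of like length and expression outside the list had a median of only -0.0236, and genes of like GC content one of -0.0158, so neither property accounts for the difference. Reads shared with pseudogenes were not tested and remain open, as does the treatment.

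How often the 35 splits of the libraries into 3 and 4 gave a result as large was counted for 4 results. For the 4 genes called by edgeR, 1 split, the real one, gave as many, and the highest other gave 1. That share of splits, 0.0286, met the bound of under 0.05 set beforehand but is the smallest possible. It makes chance less likely for that count without excluding it, as 4 results were counted without adjustment. Without NC_5 edgeR called 0 genes (977 at an unadjusted p under 0.05, 110 by DESeq2). For the 206 genes called by DESeq2, 1 split gave as many, and the highest other gave 137. The share was the same there, so chance is again less likely but not excluded. DESeq2 called 105 genes without MBZ_11 and 110 without NC_5. For the 1341 genes at an unadjusted p under 0.05, 3 splits gave as many, the highest other giving 1439, and for the 30 lists called by camera 3 splits did, the highest other giving 31. Neither of these 2 counts met the bound, so chance cannot be excluded for them either. The 1439 genes came from a split that mixes the groups (NC_5, MBZ_9 and MBZ_11 against the rest). For the lists, the other splits with as many calls kept most of the treatment grouping. They set NC_5, NC_6 and MBZ_13 (31 lists) or MBZ_9, MBZ_11 and MBZ_13 (30 lists) against the rest. Splits with 1 NC and 2 Zelnorm libraries in the group of 3 gave at most 25 lists.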

How the results depend on the processing

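The skeletal muscle covariate, the fit without the 3 libraries with the most muscle transcripts, DESeq2 on the genes tested by edgeR, and the leukocyte covariate with 1 library left out were chosen only after the result was seen. No paired analysis was possible because the columns carry none of the replicate numbers of the labels, so the planned replicate block was not run. Of the medians of lists over all alternatives, 661 kept direction and side of the threshold, 110 were weaker, 28 stronger and 52 reversed. Of the log2 fold changes of named genes, 1954 kept both, 17 were weaker, 184 stronger and 12 reversed. Cybb, Ifi204 and Ly6a each stayed past the threshold in 17 of 20 alternatives and Helz2 in 12, with log2 fold changes of 0.94 to 1.04, 0.93 to 1.28, 0.94 to 1.12 and 0.57 to 0.77. Their edgeR, limma or DESeq2 adjusted p ranged from 1.39e-12 to 0.23 for Cybb, 1.98e-12 to 0.293 for Ifi204, 2.19e-14 to 0.23 for Ly6a and 2.45e-07 to 0.23 for Helz2. Low depth limits what can be said of serotonin receptors and lymphocyte genes with few counts. Unless stated, the cause was not tested.

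The 4 genes called by edgeR (3 with a log2 fold change over 1 either way) became 34 (14) with no filter on low counts, 21 (10) with the robust fit, 206 (58) with DESeq2 on 16921 genes, 216 (59) with DESeq2 on the 12997 genes tested by edgeR, so that the filter does not account for that difference, 32 (14) at an adjusted p under 0.1 and 1341 (214) at an unadjusted p under 0.05. With the leukocyte level as covariate edgeR called 0 (0), with 694 at an unadjusted p under 0.05, and without the 3 libraries with the most muscle transcripts 0 (0), with 547 and 51 by DESeq2. Leaving out 1 library gave 0 to 161 genes (0 to 94 over 1): 0 without NC_5 (977 at an unadjusted p under 0.05, 110 by DESeq2), 161 without NC_10 and 21 without MBZ_15. With the leukocyte covariate the folds stayed near their values while their SE grew, as fewer residual degrees of freedom (4 against 5) and a level that differs between the groups leave less to estimate from: Cybb 1.02 ± 0.09 became 0.94 ± 0.15, Ifi204 1.19 ± 0.12 became 0.93 ± 0.16, Ly6a 1.01 ± 0.10 became 0.94 ± 0.16 and Helz2 0.63 ± 0.08 became 0.77 ± 0.13.

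The 30 lists called by camera became 0 with an estimated correlation (13 at an unadjusted p under 0.05), 2 with the directional and 13 with the mixed fry test, 16 with the leukocyte covariate and 26 to 34 when 1 library was left out. The exact permutation test of list levels called 0 in every setting tried, where leaving out a library leaves too few splits to pass.

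Of the reversed medians, 7 passed camera's threshold as lower (adjusted p in brackets), and none with an estimated correlation. They were endothelial (2.77e-07) and M2 macrophage (0.0145) with the leukocyte covariate, angiogenesis (0.0401) and unfolded protein (0.0151) without the 3 libraries with the most muscle transcripts, and, with 1 library left out, endothelial without NC_5 (0.0366), adipocyte without MBZ_13 (0.0404) and unfolded protein without MBZ_15 (0.0101). With a CPM of at least 1 in at least 3 libraries these were keratinocyte (-0.0048) and serotonin (-0.026). With the leukocyte level as covariate they were Dct (0.053), Cd3e (-0.022), Mki67 (0.097), Coro1a (-0.038), and the medians of pan-leukocyte (-0.038, by construction), B cell (-0.26), M2 macrophage (-0.41), dendritic cell (-0.27), neutrophil (-0.0045), endothelial (-0.36), pericyte (-0.082), keratinocyte (-0.56), chemokine (-0.010), PI3K (0.039), DNA replication (0.0089) and angiogenesis (-0.17) lists. With the skeletal muscle level as covariate they were Tyr (0.0094), Dct (0.0039), and the medians of skeletal muscle (-0.0020, by construction), PI3K (0.012), unfolded protein (-0.0064) and drug metabolism (-0.029). Without the 3 libraries with the most muscle transcripts they were Dct (0.038), M2 macrophage (-0.041), neutrophil (-0.013), endothelial (-0.074), keratinocyte (-0.13), skeletal muscle (-0.0053), PI3K (0.030), serotonin (-0.037), DNA replication (0.0049), angiogenesis (-0.11) and unfolded protein (-0.080). Leaving out 1 library gave ranges from below to above 0 for Dct (-0.037 to 0.011), Mki67 (-0.11 to 0.051), Mlana (-0.079 to 0.0069), and the medians of endothelial (-0.12 without NC_5 to 0.26 without NC_10), keratinocyte (-0.30 to 0.20), adipocyte (-0.19 without MBZ_13 to 1.04 without MBZ_9), PI3K (-0.0042 to 0.014), serotonin (-0.023 to 0.36), DNA replication (-0.028 to 0.0066), p53 (-0.038 to 0.030), angiogenesis (-0.014 to 0.11) and unfolded protein (-0.028 to 0.080) lists.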

Other observations

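The 4 tests of hypotheses here were set before their result was seen, on lists of genes put together only after the main comparison was known. The fry, camera and permutation p-values of these lists are not adjusted. Beyond the lists of the main comparison, 1 group of gene families next to the named genes was higher in the Zelnorm tumours. Of 10 testable genes of the Schlafen and Ifi200 families other than Slfn2, Ifi204 and Mnda, 9 were higher, with a median log2 fold change of 0.9278, and 6 rose adjusted over the list alone, against 0 over all genes by edgeR. Slfn1 went from 1.61 ± 0.342 to 4.10 ± 0.709 CPM and Slfn8 from 3.50 ± 0.436 to 7.60 ± 1.87 CPM (n = 3 and 4, SD). Ifi205 (log2 fold change 1.12 ± 0.31) and Pyhin1 (0.96 ± 0.27) rose adjusted over the list alone as well. The families lie in clusters of similar genes, so reads shared between them leave single values uncertain. The combined list of these families was higher (unadjusted fry p = 0.000284, and unadjusted camera p = 0.00132 with an estimated correlation). It was built around 3 genes already seen to be higher, which may share reads with its members, so it is not independent support. Each family alone was not tested, and Slfn3 was lower (-0.11 ± 0.11).

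Ctsb, a lysosomal protease, had 717 ± 40.9 CPM in NC and 926 ± 44.2 in Zelnorm tumours, higher in every Zelnorm library but not past the threshold (log2 fold change 0.37 ± 0.06, edgeR adjusted p = 0.0646). A general rise of lysosomal genes could go with it, and macrophages, whose list was higher in these tumours (median 0.69), are rich in such genes. Of 21 other lysosomal genes 16 were higher with a median of 0.0906 (fry p = 0.0377, exact permutation test of the list level p = 0.0571), short of the median of 0.1 set beforehand, so the test leaves it open. Grn (0.31 ± 0.08) and Psap (0.25 ± 0.07) rose adjusted over that list alone.

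Etv4, Etv5, Spry4 (-0.53 ± 0.12), Ier3 and Egr1 are targets of the ERK pathway and were lower in the Zelnorm tumours. Lower output of that pathway could account for them. Of 13 other output genes 9 were lower with a median of -0.0575 (fry p = 0.0204, exact permutation test of the list level p = 0.229), and Dusp6 (-0.18 ± 0.05), Spry2 (-0.24 ± 0.11) and Spred2 (-0.18 ± 0.06) were lower in every Zelnorm library, with 0 fallen adjusted over that list alone by edgeR (3 at an unadjusted p under 0.05). The median missed the -0.2 set beforehand for a lower output and lay above the -0.1 set beforehand against it, though by less than the spread of the members (quartiles -0.177 to 0.0413). By those bounds alone the median went against a lower output of the pathway. The bounds did not take in the spread of the members, which go both ways. The list also left out the 5 targets already seen to be low, which moves its median towards 0. The test therefore cannot decide, and a decrease is not excluded.

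Sterol regulatory element binding proteins drive cholesterol and fatty acid synthesis, and lower output of them might account for the lower level of cholesterol genes. Fatty acid synthesis genes had a median of -0.0641 with 10 of 14 lower (fry p = 0.0227, exact permutation test of the list level p = 0.114), between the bounds set beforehand, so this is open too. Scd2 (-0.27 ± 0.08), Fads1 (-0.18 ± 0.06) and Srebf1 (-0.20 ± 0.06) fell adjusted over that list alone.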
